A study of Mus musculus with 6 samples.

How the data were processed

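RNA was measured in EpH4 cells, a mouse mammary epithelial cell line that forms polarised monolayers. Per the labels' protocols, the cells were kept confluent for 7 days until tight junctions had formed and then received TGF-β3 at 1 ng/ml, or vehicle, in serum-free medium for 24 hours. There were 3 vehicle samples and 3 TGF-β3 samples, each on 1 array, from 3 experiments, and the RNA of 3 wells was pooled for each sample. Groups and sample numbers were taken from the sample titles.

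The platform was the Affymetrix whole-transcript gene array for mouse, version 1.1, in strip format. Per the submitters' processing notes, the authors processed them with RMA in Affymetrix Power Tools; the version is not given in the sources used here. The authors deposited 1 table of log2 signals with 241576 probe sets and 6 arrays. Several probe sets cover most genes. The log2 scale was read from the values, which lay between 2.96 and 13.07. Array medians ran from 6.56 to 6.64, so the deposited values were not exactly matched in distribution. Detection calls were not used here, so the signal at which a transcript is above background is unknown, and the number of arrays limits the precision.

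Probe sets were named through the platform's probe table. Of the 241576 probe sets, 213361 (88.3%) had 1 gene symbol, 5107 had several and 23108 were not listed; the last 2 kinds entered no gene value. Of 20893 symbols, 18496 were current in the mouse reference gene table (GRCm38.p6, used for names only), 2354 were updated through a synonym and 43 were kept as given. The probe sets of each gene were averaged per array, which gave 20848 genes with a median of 8 probe sets and no filter on low signal. Gene families with near-identical members may share probes.

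TGF-β3 was compared with vehicle with limma 3.58.1 in R 4.3.3 (lmFit and eBayes on the log2 values, no block), and p-values were adjusted by the Benjamini-Hochberg method over all genes, with a threshold of 0.05. Every difference is TGF-β3 minus vehicle in log2 units, SE is its standard error and SD the spread of the 3 arrays of a group. The adjusted p of a gene list comes from limma's camera with a preset correlation of 0.01 between genes, adjusted over 27 functional lists or over 7 cell type lists. The lists held 582 memberships, of which 562 were measured; the others were not analysed here. Lists share members, for example Itgb6 and Vcl, so their results are not independent. A gene adjusted over its list alone was adjusted over the members of that list only. This takes no account of the 27 functional and 7 cell type lists tried, so some such passes may arise by chance. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

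The lists, the main tests of genes and lists, most alternatives and the rule for naming genes were fixed before the data were examined. Most tests of explanations were chosen after the results they bear on had been seen. The rule took the 12 largest rises and the 12 largest falls among genes past the threshold with no overlap of the groups, up to 4 members with the smallest p per list, and a short set of genes named in advance. No gene met the first part. Genes named outside the rule are marked as chosen after their values were seen.

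Same-numbered samples were checked for pairing before calls were compared. The deviations from the group means correlated across genes at 0.62, 0.41 and 0.22 for the same-numbered arrays. In these deviations each array correlated best with its own number, for vehicle 3 by 0.22 against 0.17 with TGF-β3 2. In the values themselves this did not hold for number 3. There TGF-β3 3 correlated at 0.99 with vehicle 3 and at 0.995 with vehicle 1, and vehicle 3 at 0.991 with TGF-β3 2. The numbers were taken as pairs on the deviations, least securely for number 3. The paired fit, with the sample number as a replicate block, is given beside a result where it changes a call. The labels also number the samples 1, 5 and 9 for vehicle and 3, 7 and 11 for TGF-β3, in the order of the titles. The labels name 3 experiments without assigning any of these numbers to them, so the pairing rests on this order and on the check. No 2 arrays were duplicates: the SD of the difference between arrays over genes was 0.115 to 0.327.

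The alternatives were the replicate block, leaving out the genes of lowest mean signal, quantile normalization, median centring, the median or the brightest probe set of each gene, eBayes with trend and robust options, array weights, leaving out each array, testing each probe set alone, a 1.5-fold limit, camera with an estimated correlation, and fry. The block combined with quantile normalization, with the estimated correlation and with fry, and the omission of both arrays numbered 3, were added after seeing the data. Leaving out 1 array leaves its sample number in only 1 group, so that differences between the numbers enter the treatment difference.

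The scripts were tested on simulated data for this comparison, with 20848 genes of which 67 each were changed 1.5-fold and 2-fold and 66 were changed 3-fold. Without the block, 58.2% of 67 genes changed 1.5-fold and 100% of 67 changed 2-fold were recovered, with 9 false calls; with the block, 88.1% and 98.5% were recovered, with 14 false calls. Camera recovered 10 of 10 shifted lists and called 2 unshifted lists among 100 lists of independent genes. These simulations had no correlation between genes.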

Results

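The series compared EpH4 mouse mammary epithelial monolayers after 24 hours in TGF-β3 at 1 ng/ml with vehicle-treated monolayers, 3 arrays each. TGF-β3 is a secreted ligand that signals through SMAD transcription factors. The comparison asks which transcripts differ after this treatment in an epithelium with established tight junctions. Array medians lay between 6.56 and 6.64 on the log2 scale. The vehicle 3 array had a narrower range of gene signals (SD over genes 1.58) than the other 5 arrays (1.68 to 1.74).

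Monolayers treated with TGF-β3 and with vehicle had similar transcript levels. The difference was under 0.25 log2 units in 94.6% of the 20848 genes. The interferon response list rose with a median difference of 0.48 and the cell cycle list with 0.124. The list of TGF-β ligands, receptors and SMADs rose with 0.091, about as much as random lists matched on mean signal (median 0.093). Known TGF-β target genes as a list did not pass the test (median 0.057), and their difference from the ligand list was not tested. The calls of the interferon, cell cycle and ligand lists rest on a preset correlation between genes. Each was lost with an estimated correlation (adjusted p = 0.914 for each list). The estimated correlations of these lists were 0.93, 0.39 and 0.1, above the preset 0.01. How much of the loss was due to correlation between genes cannot be read from the adjusted p. Adjustment over the lists gave many lists the same 0.914, so it does not show how the p of 1 list moved. Among these was the matrix modification and proteolysis list, with an estimated correlation of -0.02 (adjusted p = 0.128 in camera with the preset). No single gene passed the threshold in limma (0 genes, 0 of them at 2-fold; lowest adjusted p = 0.684). At an unadjusted p under 0.05 there were 1076 genes, 631 higher and 445 lower, where chance gives 1042. The groups did not overlap in 12.9% of genes (10% by chance), and the sign was the same in all 3 pairs in 42.1% (25% by chance). The median half-width of the 95% interval was 0.22.

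With the replicate block, 2 genes passed, both represented by 1 probe set and named after their values were seen. Ifit3b, an interferon-induced gene, rose by 0.76 (SE 0.08, adjusted p = 0.0464) and was higher in 3 of 3 pairs. Vmn1r-ps79, a vomeronasal receptor pseudogene, fell by 1.37 (SE 0.10, adjusted p = 0.008) and was lower in 3 of 3 pairs. Its mean signal was low, at 5.95 in vehicle and 4.58 in TGF-β3. The lower quartile of all probe sets was 5.01 to 5.06 on the 6 arrays. After quantile normalization neither gene passed with the block (lowest adjusted p of all genes 0.111), an alternative added after seeing the data. Swapping the labels of pair 1 gave 3 genes. In the paired fit 2552 genes had an unadjusted p under 0.05, where chance gives 1042 if genes of similar signal share no shift.

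Of the 27 lists, 3 passed camera with the preset correlation, and 0 passed with an estimated correlation or with fry. Quantile normalization turned the sign of the median in 13 of the 27 lists, none of which had passed, and of the difference in 22 of the 148 named genes. The directions given for lists and genes that did not pass hold for the deposited values.

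**Figure D1:**
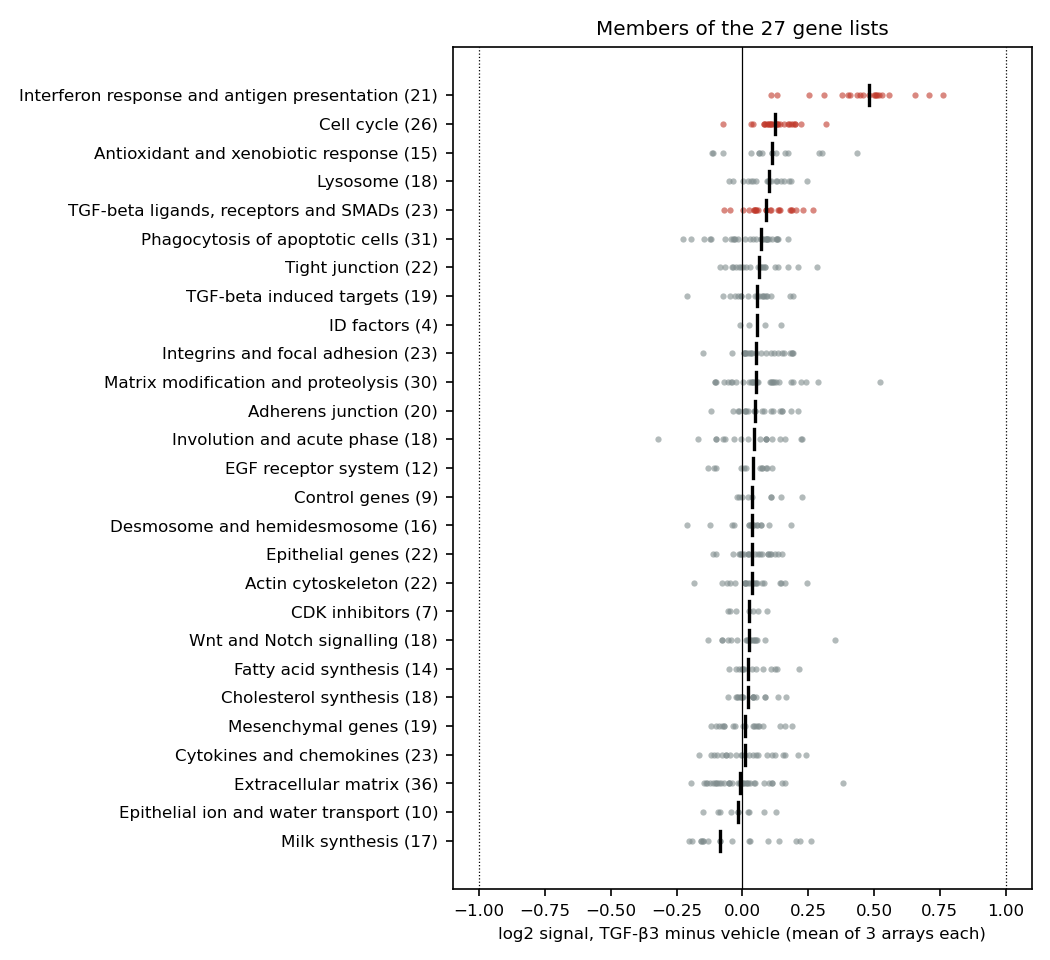
Each point is a gene, placed by its log2 difference between the means of 3 TGF-β3 and 3 vehicle arrays, in rows for the 27 lists with the number of measured members in brackets; black bars are list medians, red marks the 3 lists that passed camera with the preset correlation, and dotted lines mark 2-fold. The interferon list lies furthest to the right, with a median of 0.48, and the other medians lie between -0.085 and 0.124.

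Genes that TGF-β commonly induces through SMADs showed small differences in both directions. Of 19 measured targets, 12 were higher and 7 lower, between -0.21 and 0.19, with a list median of 0.057 (adjusted p = 0.525) that was -0.021 after quantile normalization. The inhibitory SMAD gene Smad7 had log2 signals of 7.67 ± 0.10 in vehicle and 7.72 ± 0.12 in TGF-β3 (SD, n = 3), a difference of 0.05 (SE 0.09). Klf10, an early TGF-β response gene, differed by 0.19 (SE 0.18), Itgb6, an integrin subunit of a TGF-β activating receptor, by 0.18 (SE 0.10), Smurf2, a ubiquitin ligase, by 0.11 (SE 0.09) and Bambi, a pseudoreceptor, by -0.21 (SE 0.10). None of these passed the test (0 of 19, also adjusted over the list alone), and the 95% interval of 0 of the 19 reached 2-fold.

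**Figure D2:**
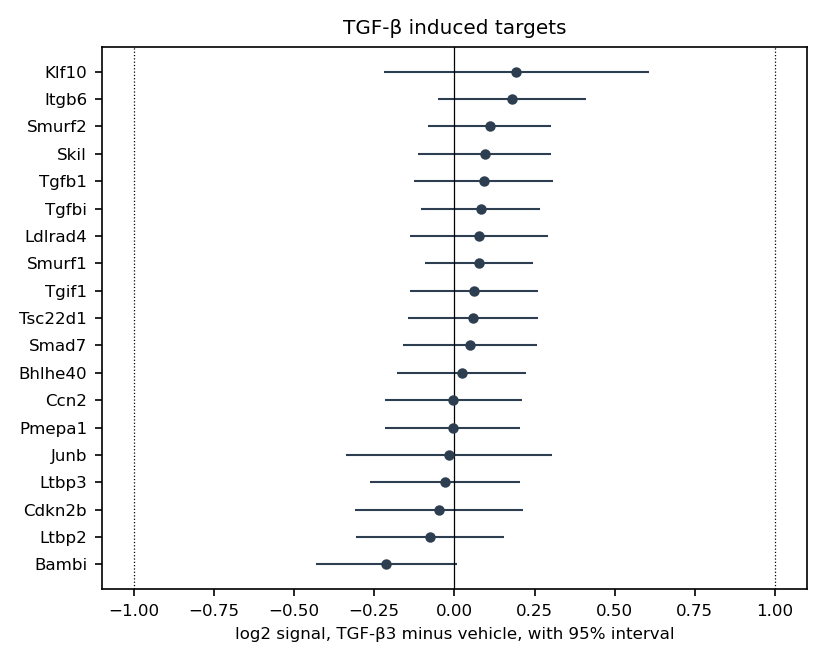
Points are the log2 differences of the 19 TGF-β induced targets between 3 TGF-β3 and 3 vehicle arrays, bars are 95% intervals from limma, and dotted lines mark 2-fold. The differences lie between -0.21 and 0.19, and no interval reaches 2-fold.

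Most genes of the TGF-β pathway itself were slightly higher, by about as much as other genes of similar signal. Of the 23 measured ligands, receptors and SMADs, 21 were higher and 2 lower, and the list rose with a median of 0.091 (adjusted p = 0.0111; adjusted p = 0.914 with an estimated correlation). The median lay at percentile 45.58 of 10000 random lists matched on mean signal, whose median was 0.093. Acvr1b, an activin type I receptor, differed by 0.27 (SE 0.10), the BMP receptor gene Bmpr1a by 0.23 (SE 0.10), the co-receptor gene Tgfbr3 by 0.20 (SE 0.08) and Eng, another co-receptor, by 0.18 (SE 0.10). Tgfb3 itself differed by 0.19 (SE 0.13). No member passed alone (0 of 23, also adjusted over the list alone). The median was 0.01 after quantile normalization (adjusted p = 0.774), 0.04 without the vehicle 3 array (adjusted p = 0.192) and 0.075 without the TGF-β3 2 array (adjusted p = 0.0634). It was 0.001 with the brightest probe set (adjusted p = 0.506), 0.042 with the median probe set (adjusted p = 0.389) and 0.05 with array weights (adjusted p = 0.157).

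Most cell cycle genes were also slightly higher. Of 26 measured members, 25 were higher, and the list rose with a median of 0.124 (adjusted p = 0.00036; adjusted p = 0.914 with an estimated correlation). Random lists matched on mean signal had a median of 0.088. Birc5, a regulator of chromosome segregation and cell survival, differed by 0.32 (SE 0.11), the spindle checkpoint kinase gene Bub1 by 0.22 (SE 0.10), the replication helicase subunit gene Mcm4 by 0.18 (SE 0.10) and the mitotic cyclin gene Ccnb2 by 0.13 (SE 0.08). No member passed alone (0 of 26, also adjusted over the list alone). The median was 0.038 after quantile normalization (adjusted p = 0.411), 0.045 with the brightest probe set (adjusted p = 0.0808) and 0.107 without the vehicle 1 array (adjusted p = 0.0796), and the call was also lost without the genes of lowest signal (0.124, adjusted p = 0.0647). It was 0.071 without the TGF-β3 3 array (adjusted p = 0.046) and 0.189 without the TGF-β3 1 array (adjusted p = 1.92e-10). The 7 CDK inhibitor genes had a median of 0.026 (adjusted p = 0.995), with Cdkn1b at 0.06 (SE 0.10), Cdkn2d at 0.09 (SE 0.09), Cdkn2a at -0.05 (SE 0.09) and Cdkn2b at -0.05 (SE 0.12).

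Interferon response and antigen presentation genes showed the largest list difference. All 21 measured members were higher in the TGF-β3 mean and 20 were higher in 3 of 3 pairs, with H2-K1 the exception, and the list rose with a median of 0.48 (adjusted p = 7.18e-05; adjusted p = 0.914 with an estimated correlation of 0.93). Irf7, a transcription factor of the interferon response, had log2 signals of 8.90 ± 0.77 in vehicle and 9.56 ± 0.59 in TGF-β3 (SD, n = 3), a 1.58-fold difference of means. The antiviral membrane protein gene Bst2 differed by 0.51 (SE 0.24), Irf9, a partner of STAT proteins, by 0.50 (SE 0.22) and Oasl2, an interferon-induced gene, by 0.38 (SE 0.23). No member passed alone (0 of 21, also adjusted over the list alone).

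The interferon difference was smaller than the spread between vehicle cultures. The mean of the 21 genes was 8.98, 8.01 and 7.72 in vehicle arrays 1, 2 and 3 and 9.22, 8.53 and 8.32 in the same-numbered TGF-β3 arrays. The vehicle means thus spanned 1.26 log2 units, against differences of 0.24, 0.52 and 0.60 within the pairs. An exact two-sided permutation test of the list mean gave p = 0.4, where the smallest possible with 3 against 3 is 0.1, and the exact sign-flip test over the pairs gave p = 0.25, the smallest that 3 pairs allow. In the paired fit, with the replicate block, 19 of the 21 genes passed adjusted over the list alone, 0 passed over all genes, and the list had an adjusted p of 7.92e-20 (adjusted p = 0.896 with an estimated correlation). The median was 0.165 without the vehicle 3 array (adjusted p = 0.192), 0.179 without the TGF-β3 1 array (adjusted p = 0.0787) and 0.807 without the vehicle 1 array. Without both arrays numbered 3, an omission that keeps the pairs whole and was chosen after seeing the data, it was 0.388 (adjusted p = 8.74e-05).

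**Figure D3:**
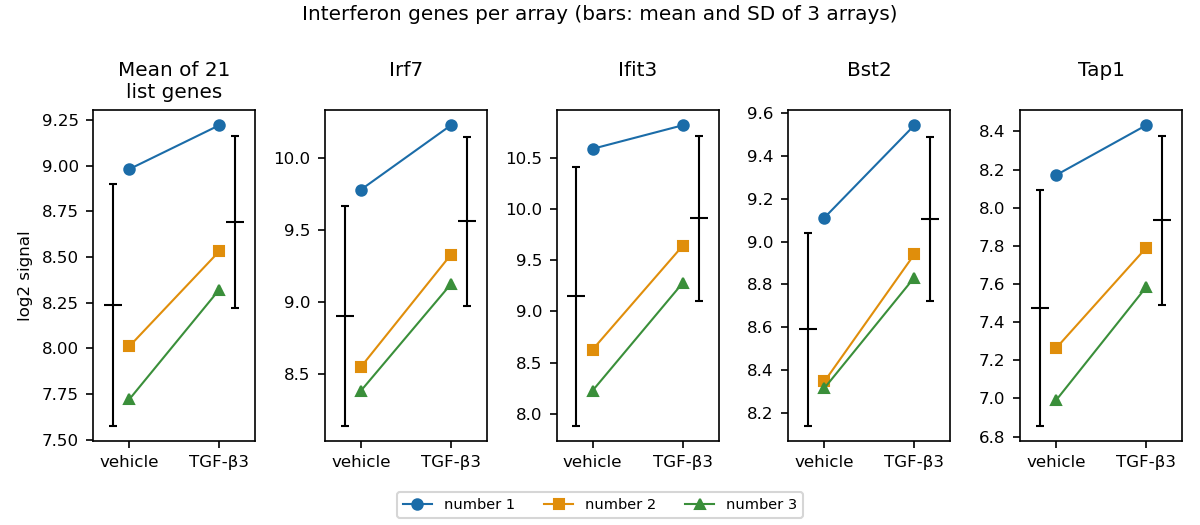
Log2 signal per array for the mean of the 21 interferon list genes and for Irf7, Ifit3, Bst2 and Tap1; lines join same-numbered samples, and black bars give the mean and SD of 3 arrays. Each line runs upward from vehicle to TGF-β3, while number 1 lies above numbers 2 and 3 in both groups, so the groups overlap.

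Junction and epithelial identity genes did not pass as lists or singly with all 6 arrays. The tight junction list had a median of 0.064 (15 of 22 higher, adjusted p = 0.357), the adherens junction list 0.047 (16 of 20 higher, adjusted p = 0.208) and the list of desmosomes and hemidesmosomes 0.036 (12 of 16 higher, adjusted p = 0.973). With the preset correlation, the tight junction list passed without the vehicle 1 array (0.107, adjusted p = 0.0428) or the TGF-β3 3 array (0.076, adjusted p = 0.046). The adherens junction list passed without the TGF-β3 3 array (0.068, adjusted p = 0.046). Each omission left a sample number in only 1 group, so the level of that number entered the difference. The tight junction list lay 0.14, -0.04 and -0.11 from its mean in numbers 1, 2 and 3. For the adherens junction list these values were 0.05, 0.01 and -0.06. Over all 6 arrays the estimated correlations of these 2 lists were 0.61 and 0.15 (adjusted p = 0.976 and 0.914 with them). Ocln, which encodes the tight junction protein occludin, differed by 0.09 (SE 0.12), the scaffold gene Tjp1 by 0.06 (SE 0.09), Cldn4 by -0.04 (SE 0.10) and Cldn3 by 0.00 (SE 0.08). Cldn23 differed by 0.28 (SE 0.11), Nectin1, an adherens junction adhesion gene, by 0.21 (SE 0.08) and the desmosomal cadherin gene Dsc3 by -0.21 (SE 0.08). E-cadherin, encoded by Cdh1, had signals of 10.20 ± 0.10 and 10.22 ± 0.05 (SD, n = 3) in vehicle and TGF-β3.

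Markers of epithelial-mesenchymal transition, a process that TGF-β can induce, did not pass the test. The mesenchymal list had a median of 0.011 (11 of 19 higher, adjusted p = 0.995) and the epithelial list 0.036 (15 of 22 higher, adjusted p = 0.536). The intermediate filament gene Vim differed by -0.03 (95% interval -0.29 to 0.23), Fn1, which encodes fibronectin, by 0.00 (-0.20 to 0.20), and the transcription factor genes Snai1 and Zeb1 by 0.14 (SE 0.10) and -0.12 (SE 0.08). The 4 ID factor genes, targets of BMP signalling, had a median of 0.056 (adjusted p = 0.6).

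Among matrix and protease genes, Mmp13 differed most. This collagenase gene had signals of 5.75 ± 0.05 in vehicle and 6.27 ± 0.24 in TGF-β3 (SD, n = 3), a difference of 0.52 (SE 0.12) with no overlap of the groups. It did not pass over all genes (adjusted p = 0.684). Adjusted over the list alone, without account of the number of lists tried, it was the 1 of 30 members to pass (adjusted p = 0.0496). Its list had a median of 0.052 (22 of 30 higher, adjusted p = 0.128; 0.095 and adjusted p = 0.046 without the TGF-β3 3 array), with Mmp9 at 0.29 (SE 0.13), Loxl3 at 0.24 (SE 0.09) and the plasminogen activator gene Plau at 0.18 (SE 0.08). The extracellular matrix list had a median of -0.009 (15 of 36 higher, adjusted p = 0.497). Its member Tnc, which encodes tenascin C, differed by 0.38 (SE 0.15) and passed adjusted over the list alone with the replicate block (adjusted p = 0.0469), and the collagen gene Col4a2 differed by -0.20 (SE 0.08). Integrins and focal adhesion genes had a median of 0.053 (21 of 23 higher, adjusted p = 0.128; 0.113 and adjusted p = 0.00691 without the vehicle 2 array) and actin cytoskeleton genes 0.036 (17 of 22 higher, adjusted p = 0.525). Itga5, an integrin subunit gene, differed by 0.19 (SE 0.10) and the non-muscle myosin gene Myh10 by 0.25 (SE 0.09).

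Genes for the uptake of apoptotic cells, a function of mammary epithelium after lactation, did not pass. Their list had a median of 0.069 (20 of 31 higher, adjusted p = 0.587). The bridging protein gene Mfge8 differed by 0.03 (SE 0.10), the receptor tyrosine kinase genes Axl and Mertk by 0.07 (SE 0.08) and -0.12 (SE 0.10), Itgav and Itgb3 by 0.13 (SE 0.10) and 0.01 (SE 0.09), and the scavenger receptor gene Scarb1 by 0.17 (SE 0.10). Lysosome genes had a median of 0.101 (16 of 18 higher, adjusted p = 0.0892), including the cholesterol transporter gene Npc1 at 0.24 (SE 0.09), and passed without the vehicle 2 array (0.096, adjusted p = 0.0375) or the TGF-β3 3 array (0.143, adjusted p = 0.00844). Milk synthesis genes had a median of -0.085 (7 of 17 higher, adjusted p = 0.463), with the milk protein genes Csn1s1, Wap and Csn2 at -0.20 (SE 0.09), -0.19 (SE 0.10) and -0.13 (SE 0.10). The vehicle means of these 3 genes were low, at 4.88, 5.57 and 5.18. On the vehicle 3 array the fifth of genes with the lowest signal lay 0.13 above their mean over the arrays. Involution and acute phase genes had a median of 0.044 (10 of 18 higher, adjusted p = 0.995), with Saa1 at -0.32 (SE 0.12).

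The antioxidant and xenobiotic response list, which includes targets of NRF2, had a median of 0.111 (12 of 15 higher, adjusted p = 0.0892). It passed without the vehicle 1 array (0.176, adjusted p = 0.0428), without the TGF-β3 2 array (0.157, adjusted p = 0.0343) and with the brightest probe set (0.11, adjusted p = 0.0252). The list lay 0.09, -0.05 and -0.04 from its mean in numbers 1, 2 and 3, and leaving out 1 array lets these levels enter the difference. Nqo1, a quinone reductase gene, differed by 0.43 (SE 0.14), the glutathione transferase gene Gsta4 by 0.30 (SE 0.08) and the cystine transporter gene Slc7a11 by 0.29 (SE 0.15). No member passed adjusted over the list alone. With the replicate block, Nqo1, Gsta4 and Slc7a11 did so (adjusted p = 0.0263, 0.0263 and 0.0386), without account of the number of lists tried. Cholesterol synthesis genes had a median of 0.02 (11 of 18 higher, adjusted p = 0.587; 0.086 and adjusted p = 0.0311 without the TGF-β3 1 array) and fatty acid synthesis genes 0.021 (10 of 14 higher, adjusted p = 0.525), with Sqle at 0.16 (SE 0.10) and Acaca at 0.21 (SE 0.14). Cytokine and chemokine genes had a median of 0.01 (13 of 23 higher, adjusted p = 0.995), with Il18 at 0.21 (SE 0.10). Wnt and Notch genes had a median of 0.025 (adjusted p = 0.995) and the EGF receptor system 0.039 (adjusted p = 0.995), and in both the camera direction was down against the other genes although the median was above 0. The Notch target gene Hey1 differed by 0.35 (SE 0.28) and passed adjusted over the list alone with the replicate block (adjusted p = 0.0326). Ion and water transport genes had a median of -0.015 (adjusted p = 0.701) and the 9 control genes 0.037 (adjusted p = 0.362).

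Markers of cell types did not pass as lists. The lymphocyte list had a median of -0.172 (3 of 4 lower, adjusted p = 0.188), the endothelial list -0.068 (adjusted p = 0.194), the basal and myoepithelial list -0.025 (adjusted p = 0.641), the macrophage list -0.123 (adjusted p = 0.753), the luminal list -0.022 (adjusted p = 0.753), the adipocyte list -0.013 (adjusted p = 0.753) and the fibroblast list 0.013 (adjusted p = 0.977). The luminal keratin gene Krt8 differed by 0.06 (SE 0.08) and the pan-leukocyte gene Ptprc by -0.22 (SE 0.11). Vehicle means were low for Ptprc (5.45) and for the lymphocyte (4.82) and endothelial (5.09) lists. The part of the raised low signals of the vehicle 3 array in these falls was not tested. Csf1r, a macrophage receptor gene, differed by 0.36 (SE 0.15) and Pdgfrb, a fibroblast receptor gene, by 0.28 (SE 0.14). With the replicate block both passed adjusted over the list alone (adjusted p = 0.00635 and 0.0421), without account of the number of lists tried.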

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

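The block combined with another choice, and the omission of both arrays numbered 3, were chosen after seeing the data. The count of genes past the threshold was 0 in limma and in each alternative except 2: with the replicate block it was 2 (1 at 2-fold), and without the vehicle 1 array it was 1 (1 at 2-fold), so leaving out an array gave 0 to 1. That gene, Obox2 (-1.68, SE 0.14, adjusted p = 0.021), was named after its values were seen. At an unadjusted p under 0.05 the count ran from 247 without both arrays numbered 3 to 3796 without the vehicle 1 array, and testing each of 241576 probe sets alone called 0, with 10027 at an unadjusted p under 0.05. The 3 called lists became 1 without the genes of lowest signal, 1 after quantile normalization (also 1 with the block), 0 with an estimated correlation and 0 with fry (0 and 0 with the block), and 1 to 7 when an array was left out: 5 without vehicle 2, 1 without vehicle 3 and 7 without TGF-β3 3. The replicate block on its own changed no list call and, beyond Ifit3b and Vmn1r-ps79 (0.76 and -1.37), no call of a named gene over all genes. The interferon median of 0.48 lost its call with an estimated correlation (adjusted p = 0.914; 0.896 with the block) and fry (adjusted p = 0.751; 0.365 with the block) and ran from 0.165 to 0.807 when an array was left out, with the call lost without vehicle 3 or TGF-β3 1 but kept without both arrays numbered 3 (0.388, adjusted p = 8.74e-05). The cell cycle median of 0.124 lost its call with the same tests (adjusted p = 0.914 and 0.68; 0.896 and 0.489 with the block), without the genes of lowest signal (0.124, adjusted p = 0.0647), after quantile normalization (0.038, also with the block) and with the brightest probe set (0.045), and ran from 0.071 to 0.189 when an array was left out (0.08 without both arrays numbered 3, adjusted p = 0.0448, call kept). The TGF-β ligand, receptor and SMAD median of 0.091 lost its call with the same tests (adjusted p = 0.914 and 0.68; 0.896 and 0.489 with the block), without the genes of lowest signal (0.098), after quantile normalization (0.01, also with the block), with the median probe set (0.042), the brightest probe set (0.001), array weights (0.05) and without both arrays numbered 3 (0.039), and ran from 0.04 to 0.131 when an array was left out. The cause was not tested for these losses, apart from the tests of signal range given under other observations. Of the 24 lists not called, 7 were called in at least 1 alternative, 11 calls in all, each upward and 10 of them with an array left out. All 11 used the preset correlation. In the 10 calls with an array left out, differences between the sample numbers entered the treatment difference. Of 148 named genes, 146 passed in no setting and 65 changed sign in at least 1 alternative. Without detection calls, differences of genes with low signal could not be set against background.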

Other observations

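Most of the tests below were chosen only after the result they bear on had been seen: the splits for genes, the pair tests of the interferon list, the interval and pair tests of the TGF-β targets, the tests of the vehicle 3 array, and those of gene parts.

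Interferon genes differed more between the sample numbers than between treatments. In the paired fit, 246 genes differed between the 3 numbers at an adjusted p under 0.05, and 179 of them were highest in number 1. They included 17 of the 21 interferon list genes. Rsad2, an antiviral interferon-induced gene, had mean signals of 9.40, 7.82 and 7.44 in numbers 1, 2 and 3, and Nos2, which encodes inducible nitric oxide synthase, had 7.83, 6.56 and 6.54. The tight junction gene Cldn1 (7.59, 6.51 and 6.63) and the stress-response transcription factor gene Atf3 (8.56, 6.99 and 7.13) were also highest in number 1. These genes were named after their values were seen. A further 74 interferon family genes outside the list, picked by symbol after Ifit3b had been seen and so no independent evidence, had a median TGF-β3 difference of 0.29, and 49 of them were higher and 7 lower in 3 of 3 pairs.

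The interferon list was higher in TGF-β3 in each pair. The narrow signal range of the vehicle 3 array was argued against as the whole cause, since pairs 1 and 2, which lack that array, kept median differences of 0.196 and 0.492 after quantile normalization. An intensity-dependent difference between arrays was also argued against, since the list median lay at percentile 100 among 10000 random lists matched on mean signal, whose median was 0.079. In the paired fit, 19 of 21 genes passed adjusted over the list alone. Camera with the preset correlation, which takes members as nearly independent, gave an adjusted p of 7.92e-20. The adjusted p was 0.896 with the estimated correlation of 0.44 and 0.365 with fry. The value of 0.896 decides nothing, because adjustment over the lists gave most lists this same value. Among these was the matrix modification and proteolysis list, whose estimated correlation with the block was 0.01, equal to the preset (adjusted p = 0.0753 in camera with the preset). Uneven interferon levels between cultures and an effect of TGF-β3 thus cannot be told apart, and the exact sign-flip test decides nothing, since its p of 0.25 is the smallest that 3 pairs allow.

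The TGF-β ligand, receptor and SMAD list shifted about as much as other genes of similar signal, and the cell cycle list by more than the median of such genes. For the ligand list the median of 0.091 lay at percentile 45.58 of matched random lists (median 0.093), which is consistent with an intensity-dependent difference between the arrays; the vehicle 3 array alone remains open, with 0.04 left without it. For the cell cycle list the median of 0.124 lay at percentile 98.41 (random median 0.088), above the upper bound of 0.12 from the random lists by less than the SE over members of 0.014; this bound, set beforehand, took no account of this SE, which was added after the value was seen, and the explanation stays open. The vehicle 3 array was argued against only as the whole cause for this list, as the median was 0.127 without it (adjusted p = 0.000164) and 0.08 without both arrays numbered 3 (SE over members 0.014, adjusted p = 0.0448); a part in the difference stays open. Quantile normalization ended the cell cycle call by moving the median from 0.124 to 0.038 (SE over members 0.014 and 0.013), whereas median centring left it at 0.125 (adjusted p = 0.000585), so the call ended because most of the difference was lost when the full distributions of the arrays were matched.

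No TGF-β induced target passed the threshold. Too low a precision for a 2-fold rise was argued against, as 0 of 19 intervals reached 2-fold and 1, that of Klf10, reached a 1.5-fold rise. Labels swapped within a pair were argued against, as the median of the targets was at most 0.081 in size in any pair. With the brightest probe set the median of the targets was 0.001, but this cannot decide on dilution by averaging probe sets. That choice also lowered the interferon median, from 0.48 to 0.349, and the cell cycle median, from 0.124 to 0.045. Rises under 1.5-fold, dilution by averaging probe sets, a response that had ended by 24 hours and a weak response of these cells stay open.

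Splits of the 6 arrays into 3 and 3 number 10, too few for a share under 0.05. For genes past the threshold the real value was 0 and the highest other 0 (10 of 10 splits as large), likewise at 2-fold (10 of 10). For lists the real value was 3 and the highest other 11 (6 of 10 splits as large); that split set vehicle 1, vehicle 2 and TGF-β3 1 against the rest, without regard to the pairs. Among the splits that part all 3 pairs, in the paired fit, the real one gave 2 genes and 3 lists, and swapping pair 1, 2 or 3 gave 3, 0 and 0 genes and 2, 0 and 0 lists. At an unadjusted p under 0.05 the real labels gave 2552 genes and these swaps 743, 358 and 190. Chance gives 1042 if genes of similar signal share no shift. These 4 splits are too few for a share under 0.05.

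Whether TGF-β3 changed the use of parts of genes could not be answered. The test first run, limma's diffSplice, called 25 genes without and 113 with the replicate block, and 14 to 39 when a pair was swapped, but on simulated data it made 159 false calls among 2000 genes and was set aside after its counts had been seen. Its replacement, each probe set against the rest of its gene with its own variance, made 0 false calls but recovered 0% of 200 genes with 1 probe set changed 2-fold. It called 0 of 16988 genes with the block, with 478 at an unadjusted p under 0.05, and 4 of the 4 splits that part the pairs gave as many (highest other 0), too few for a share under 0.05.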
